A study of Rattus norvegicus with 6 samples.

How the data were processed

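The series holds 6 RNA-seq libraries of primary dorsal root ganglion neurons, labelled as rat, 3 given extracellular vesicles from innervated muscle (EVMu) and 3 given vesicles from acutely denervated muscle (EVadMu). Per the labels' protocols, RNA was extracted with TRIzol, poly(A)-selected on oligo(dT) beads, fragmented, reverse transcribed from random hexamers and amplified by PCR. The protocol names no step that marks strand. The submitters' processing notes name CASAVA 1.8, HISAT2, SAMtools and featureCounts, without their roles or settings, and the genome build mm39, which is a mouse build. All 56748 gene identifiers in the table are mouse Ensembl identifiers. The handling of reads with several hits, the strand setting and the annotation release are not given in the sources used here. The species of the label and that of the identifiers and build differ, and which of them describes the cells was not tested. If rat reads were counted on a mouse genome, reads would be lost where the sequences differ, by an amount that can vary between genes, and whether the loss was equal in both groups was not tested. A rat gene table (GRCr8) was used only for names and gene order, and 13872 of the tested gene names (81.6%) were also found in it. No genome coordinates are given here, since no annotation of the build was used.

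The deposited values are whole-number counts of reads per gene, not normalised by the authors. Library totals were 14955967, 14853115 and 17019877 counts for EVMu replicates 1 to 3 and 16699450, 16551228 and 16605725 for EVadMu replicates 1 to 3. Groups and replicate numbers were taken from the sample titles. Within-group Pearson correlations of log CPM were 0.989 to 0.992 and between-group correlations 0.851 to 0.854, and the first principal component of the 500 most variable genes held 98.3% of their variance and parted the groups. Pairs of libraries of a group differed by 1.96 to 2.58 times the variance of counting noise, so no pair was counted as 1 library deposited in 2 copies. The ratio was still 1.82 to 2.24 for genes with under 200 counts over the pair. This does not show that the libraries came from separate cultures, or that none was sequenced 2 times.

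Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0. Of the table's genes, 20965 had no counts in any library, and 16993 passed edgeR's default expression filter (minimum count 10, minimum total 15). Libraries were scaled with TMM factors, and EVadMu was compared with EVMu by the quasi-likelihood F-test with Benjamini-Hochberg adjustment and a threshold of 0.05, with a second count at a log2 fold change of at least 1. The biological coefficient of variation was 4.1%. Levels are TMM-normalised CPM with the SD over 3 libraries, and log2 fold changes carry the model's standard error. Where a group had no counts, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval is given.

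The groups, test, 33 gene lists and the rule for named genes were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 on log CPM (prior count 2), adjusted over the lists with at least 5 tested members, and list medians carry 95% bootstrap intervals from 10000 resamples of the members. Named genes were the 10 largest rises and 10 largest falls among called genes with a symbol, a mean CPM of at least 1 and no overlap between the groups, plus up to 4 called members of each list with the smallest p. Lists appear in the order of their test. Some genes that the rule picks are not reported here. Lists share some genes, among them L1cam, Slc7a11, Hk2, Slc2a1, Snap25, Ddit3 and Gadd45a. Members named for going against their list, the 7 lists of the closing section and Gapdh, mt-Rnr1 and mt-Rnr2 were added after values were seen.

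In counts simulated from the real means and library sizes, with 200 genes changed, 16658 genes passed the filter. The test recovered 62% of genes changed 1.25-fold, 72% at 1.5-fold, 90% at 2-fold and 98% at 4-fold (50 genes each), where the 2 changed genes that the filter removed count as not recovered, and made 8 false calls among 16460 unchanged genes. The simulated changes had random signs and all genes shared a common dispersion. These rates therefore do not carry over to the real data, where 80% of tested genes were called. Alternatives were RLE and upper-quartile factors, no filter, a stricter filter (mean CPM of at least 1 and 20 counts in 3 libraries), the replicate number as a block, DESeq2, limma-voom, leaving out each library, camera with an estimated correlation, and fry. Library sizes without scaling factors were added after seeing the data. Gene length and GC content were not tested, since no annotation of the build was used, and all sample columns of the table entered the analysis.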

Results

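Primary neurons of the dorsal root ganglion, the cluster of sensory nerve cell bodies beside the spinal cord, were given extracellular vesicles released by muscle. Vesicles came from muscle with an intact nerve supply (EVMu, 3 libraries) or from muscle whose nerve supply had been lost acutely (EVadMu, 3 libraries), and poly(A)-selected RNA was sequenced. Gene counts summed to between 14853115 and 17019877 per library. The comparison asks which transcripts differed between neurons that received the 2 kinds of vesicle, with EVMu as the reference, so that a positive log2 fold change means a higher level in EVadMu. The series has no group without vesicles, so a fall in EVadMu cannot be told from a rise in EVMu. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Any difference in culture preparation or sequencing batch between the groups could not be told from the kind of vesicle.

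The groups differed across most of the measured transcriptome. The cytokine gene Gdf15 rose from 4.01 ± 1.28 to 437.6 ± 13.2 CPM (read counts normalised to library size; SD, n = 3 per group), a log2 fold change of 6.78 ± 0.073 (SE), and the metabolic hormone gene Fgf21 rose from 0.229 ± 0.082 to 24.6 ± 2.63 CPM. The collagen gene Col3a1 fell from 1415 ± 12.2 to 3.82 ± 0.90 CPM, the inter-alpha-trypsin inhibitor chain gene Itih5 from 453 ± 7.12 to 1.15 ± 0.38 CPM, and the mitotic kinase gene Aurkb from 58.6 ± 4.39 to 0.083 ± 0.072 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13597 of 16993 tested genes passed an adjusted p of 0.05 (80%), 6658 higher and 6939 lower in EVadMu. A change of at least 2-fold was found for 6991 of them (41.1%), 2992 higher and 3999 lower. The levels of the 3 libraries of one group lay wholly outside those of the other for 13717 tested genes (80.7%), where chance gives 10%. All levels are relative, since no measure of total RNA entered the comparison. Scaling placed the median log2 fold change of all tested genes at -0.02, and small rises and falls depend on that placement. Without scaling factors 6030 genes were called higher.

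Among the other genes with the largest rises, Sstr5, a somatostatin receptor gene, went from 0.078 ± 0.086 to 9.01 ± 0.58 CPM, and Asmt, the last enzyme of melatonin synthesis, from 0.081 ± 0.028 to 5.77 ± 0.60 CPM. Ppp1r3g, a glycogen-targeting phosphatase subunit gene, had no counts in EVMu and was at least 70.8-fold higher in EVadMu, taking 3 counts over the EVMu group as the floor. The predicted gene Gm42614 was at least 53.2-fold higher on the same floor. The olfactory receptor gene Olfr1392 had 2 counts over the EVMu libraries and a ratio of 148 (95% counting interval 40.7 to 1230). The trypsin family gene Try5 had a ratio of 93.1 (31.5 to 454) and the aldose reductase family gene Akr1b7 one of 55.9 (15.1 to 467). Usp17ld, of a multicopy deubiquitinase family, went from 0.086 ± 0.15 to 4.47 ± 0.21 CPM. All these genes passed edgeR's adjusted threshold, but Try5, Olfr1392 and Usp17ld belong to families whose near-identical members can share reads, so their levels are uncertain.

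Among the other largest falls, Npy2r, a neuropeptide Y receptor gene of sensory neurons, was at 13.6 ± 0.92 CPM in EVMu and had no counts in any EVadMu library, at least 216-fold lower. The itch receptor gene Mrgprx1 was at least 68.9-fold lower and the related receptor gene Mrgprf fell from 48.0 ± 1.5 to 0.083 ± 0.14 CPM. The eosinophil lectin gene Siglecf was at least 37.4-fold lower, and the predicted genes Gm20667 and Gm13749 were at least 58.4-fold and at least 40.7-fold lower. Cenpf, a centromere protein gene, fell from 165 ± 3.56 to 0.42 ± 0.24 CPM. Mrgprx1 has close paralogs and its reads may be split among them. Intervals and floors cover counting error only.

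Of 33 gene lists fixed beforehand, 24 moved against the other genes in limma's camera test at a preset correlation of 0.01, 13 up and 11 down. With an estimated correlation 18 of these 24 also passed camera, at adjusted p of 0.0268 to 0.0475. The far smaller adjusted p given for these lists below thus depend on the preset correlation. Counts of members adjusted over the list alone equalled those over all genes in 29 lists, and the other 4 are given where they occur. Members that went against their list were named after their values had been seen. Other splits of the 6 libraries, in which each side mixed both groups, gave 0 called genes in edgeR's test (33 to 63 at an unadjusted p under 0.05) but 22 to 25 called lists, so the number of called lists does not set the real grouping apart. Mixed sides keep part of the group contrast and add the rest to the spread within a side. Neither count therefore decides whether chance gave the real calls.

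**Figure D1:**
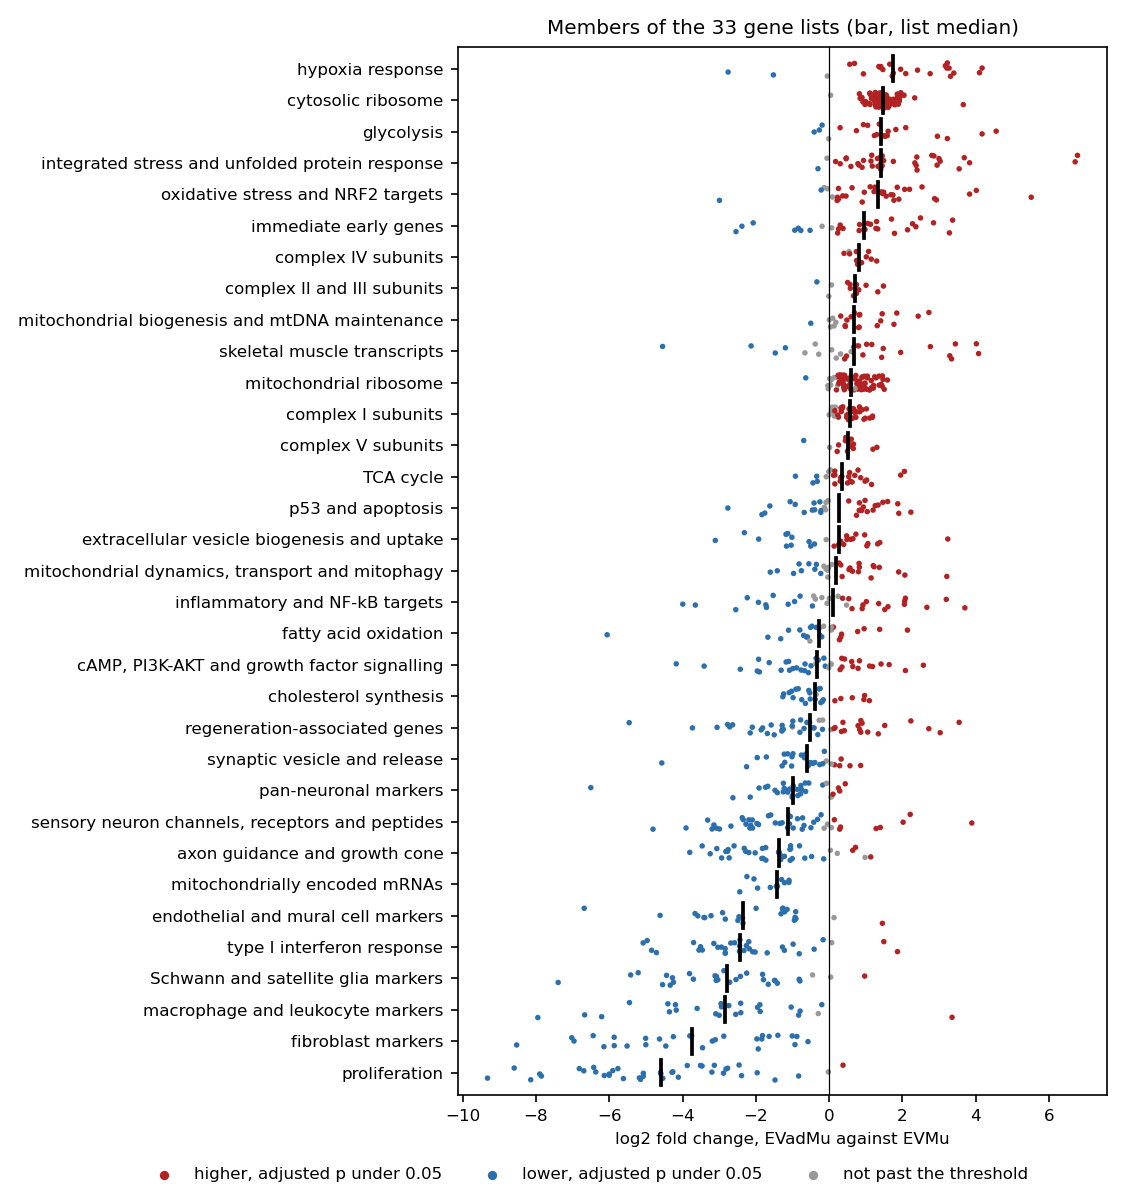
Log2 fold change of EVadMu against EVMu (horizontal axis) for each tested member of the 33 gene lists (points, coloured by direction where the adjusted p was under 0.05), with the list median as a black bar. Proliferation genes had the lowest median (-4.60) and hypoxia response genes the highest (1.75).

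Genes of the cytosolic ribosome rose nearly as a block. Of 82 tested, 81 were higher and 0 lower, over all genes and adjusted over the list alone, with a median log2 fold change of 1.46 (95% bootstrap interval 1.41 to 1.52; camera adjusted p = 4.05e-18). Rpl4 rose from 576 ± 2.86 to 1948 ± 60.8 CPM (SD, n = 3), and Rpl10 and Rps14 rose by 1.79 ± 0.029 and 1.86 ± 0.031 on the log2 scale (SE). The exception was Rps4l at 0.04, which did not pass. Ribosomal protein genes have many processed pseudogenes that can share their reads. In the same libraries the share of counts on mitochondrial ribosomal RNA was higher, 0.565 to 0.604% against 0.0524 to 0.0541%. Markers of fibroblasts, of Schwann and satellite glia and of macrophages and leukocytes were lower there (medians -3.75, -2.79 and -2.84). With 2 groups, all features that differ between them go together. Such values, here and below, therefore show no particular link to a list.

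Cell division genes had the lowest median of the 33 lists. Of 40 proliferation genes, 38 were lower and 1 higher, over all genes and adjusted over the list alone, with a median of -4.60 (-5.69 to -3.69; camera adjusted p = 7.78e-12). Mki67, the gene of the proliferation antigen Ki-67, fell from 446 ± 5.43 to 1.92 ± 0.11 CPM and the topoisomerase gene Top2a from 434 ± 9.81 to 1.53 ± 0.27 CPM, while the cytokinesis gene Prc1 had a log2 fold change of -5.61 ± 0.076. The replication clamp gene Pcna rose by 0.38, and the helicase subunit gene Mcm7 was at -0.02 and did not pass. Markers of fibroblasts and of Schwann and satellite glia, cells that can divide in such cultures, were lower in the same libraries (medians -3.75 and -2.79).

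The integrated stress and unfolded protein response was higher in EVadMu. Of 37 genes, 35 rose and 1 fell, also when adjusted over the list alone, with a median of 1.41 (1.16 to 2.38; camera adjusted p = 1.3e-10). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 835 ± 14.4 to 6068 ± 98.1 CPM. Ppp1r15a, which directs removal of the phosphate from the initiation factor eIF2α, rose from 76.6 ± 2.13 to 988 ± 9.37 CPM, and the amino acid transporter genes Slc3a2 and Slc7a11 rose by 2.95 ± 0.031 and 3.83 ± 0.040 on the log2 scale. The disulfide isomerase gene Pdia6 fell by 0.30, and Pdia4 was at -0.06 and did not pass. As for the ribosome, the libraries in which this list rose held the higher share of mitochondrial ribosomal RNA (0.565 to 0.604%). Their fibroblast and glia markers were lower (medians -3.75 and -2.79), as were pan-neuronal markers (median -0.99).

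**Figure D2:**
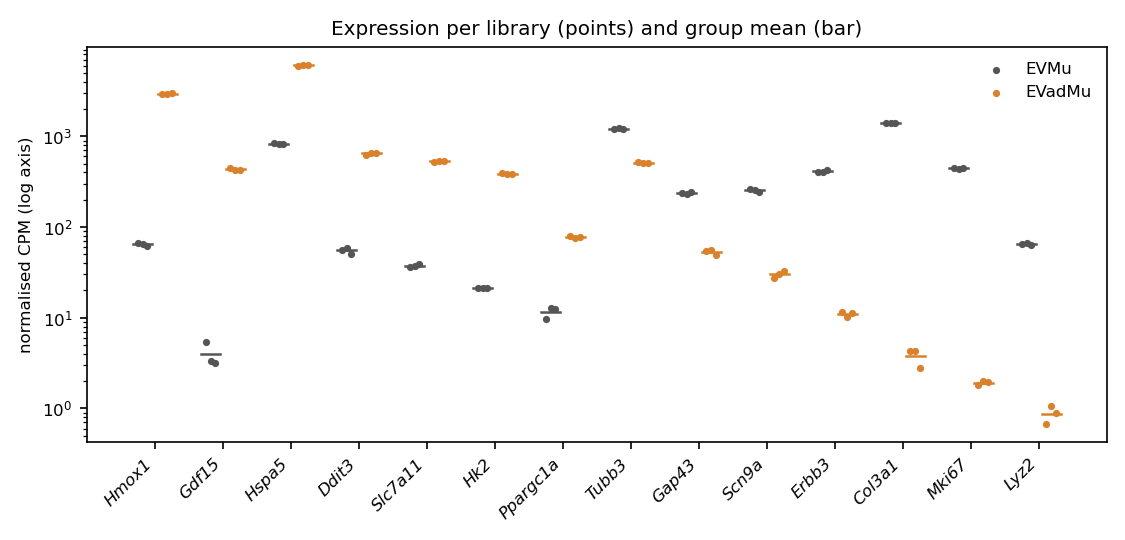
Normalised CPM on a log axis for selected genes in each of the 3 EVMu and 3 EVadMu libraries (points), with the group mean as a bar. The libraries of a group lay close together and the groups were apart for each gene shown, as for Hmox1 (64.6 against 2957 CPM) and Mki67 (446 against 1.92 CPM).

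All 29 tested fibroblast markers were lower in EVadMu, over all genes and adjusted over the list alone, with a median of -3.75 (-5.00 to -1.97; camera adjusted p = 2.24e-10). The fibrillar collagen gene Col1a1 fell from 1283 ± 21.4 to 14.8 ± 0.17 CPM, the matrix gene Postn from 1068 ± 12.8 to 18.3 ± 2.83 CPM and Col6a3 from 403 ± 3.88 to 5.68 ± 0.82 CPM (SD, n = 3). These are markers of a cell type other than the neurons named in the labels, and the neuronal tubulin gene Tubb3 stood at 1217 ± 14.6 CPM in the same EVMu libraries.

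Mitochondrial ribosome genes rose by a smaller amount than those of the cytosolic ribosome. Of 80 tested, 68 were higher and 1 lower, also when adjusted over the list alone, with a median of 0.59 (0.43 to 0.81; camera adjusted p = 4.3e-09). Mrps18a rose from 28.6 ± 2.00 to 78.2 ± 1.91 CPM and Mrpl38 from 29.4 ± 1.10 to 78.7 ± 2.60 CPM, with Mrps23 and Mrpl9 up by 1.28 ± 0.058 and 1.21 ± 0.059 on the log2 scale. Mrps25 fell by 0.64. A few rows of this list are annotated pseudogenes that may share reads with their parent genes. Alongside, the mitochondrial ribosomal RNA share was higher (0.565 to 0.604% against 0.0524 to 0.0541%), mitochondrially encoded mRNAs were lower (median -1.43), and so were fibroblast and glia markers (medians -3.75 and -2.79).

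Schwann and satellite glia markers were lower, 27 of 30 with 1 higher (28 and 1 when adjusted over the list alone), at a median of -2.79 (-3.41 to -1.8; camera adjusted p = 1.96e-08). The neuregulin receptor gene Erbb3 fell from 411 ± 8.98 to 11.1 ± 0.76 CPM and the adhesion gene Cadm4 from 1138 ± 87.0 to 48.8 ± 0.94 CPM. L1cam, an adhesion gene that neurons also express, had a log2 fold change of -2.71 ± 0.037. The endothelin receptor gene Ednrb rose by 0.97, while S100b (0.04) and Shh (-0.45) did not pass over all genes.

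Type I interferon response genes were lower, 32 of 35 with 2 higher, also when adjusted over the list alone, at a median of -2.44 (-2.84 to -2.08; camera adjusted p = 2.13e-07). Parp14, an interferon-induced ADP-ribosyltransferase gene, fell from 113 ± 2.57 to 4.31 ± 0.13 CPM, Oasl2 from 65.0 ± 1.74 to 5.71 ± 0.87 CPM and the guanylate-binding protein gene Gbp2 from 51.4 ± 2.35 to 4.66 ± 0.049 CPM, and the signal transducer gene Stat2 fell by 2.02 on the log2 scale. The antiviral genes Rsad2 and Isg20 rose by 1.49 and 1.87, and Oas1a was at 0.07 and did not pass. Macrophage and leukocyte markers were lower in the same libraries (median -2.84).

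Axon guidance and growth cone genes were lower, 35 of 41 with 3 higher, also when adjusted over the list alone, at a median of -1.37 (-1.84 to -1.07; camera adjusted p = 2.33e-07). The semaphorin receptor gene Plxna4 fell from 338 ± 7.11 to 30.6 ± 0.75 CPM, the membrane-actin linker gene Marcks from 713 ± 11.9 to 156 ± 4.49 CPM and the ephrin receptor gene Ephb2 from 121 ± 2.58 to 8.68 ± 0.63 CPM, with Sema6d at -3.25 ± 0.055 on the log2 scale. The receptor gene Epha4 and the genes Efna1 and Unc5b rose by 1.14, 0.72 and 0.65. Dcc (0.98), Cap2 (0.22) and Plxna1 (0.04) did not pass. Glia and fibroblasts express several of these genes, and their markers were lower alongside (medians -2.79 and -3.75).

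Oxidative stress and NRF2 target genes were higher, 29 of 34 with 2 lower (30 and 2 when adjusted over the list alone), at a median of 1.34 (0.63 to 1.74; camera adjusted p = 3.2e-07). Heme oxygenase, Hmox1, rose from 64.6 ± 2.27 to 2957 ± 55.5 CPM, a log2 fold change of 5.52 ± 0.034 (SE), and the cystine transporter gene Slc7a11 from 37.4 ± 1.30 to 534 ± 4.83 CPM. The ferritin genes Fth1 and Ftl1 rose from 1059 ± 6.11 to 3611 ± 61.0 CPM and from 479 ± 33.5 to 2779 ± 92.4 CPM, where Ftl1 can share reads with its copies. Among superoxide dismutases, the extracellular Sod3 and the mitochondrial Sod2 fell, with log2 fold changes of -2.99 and -0.22. Txn1 (0.09), Keap1 (-0.05) and Gpx1 (-0.13) did not pass over all genes.

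Hypoxia response genes had the highest list median, 1.75 (1.39 to 3.17), with 22 of 25 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 4.68e-07). The growth factor gene Vegfa rose from 54.9 ± 1.57 to 531 ± 13.4 CPM and the oxidoreductase gene Ero1a from 100.2 ± 7.60 to 995 ± 37.2 CPM. Hk2, which catalyses the first step of glycolysis, rose from 21.3 ± 0.066 to 386 ± 5.16 CPM, and the glucose transporter gene Slc2a1 from 84.2 ± 2.77 to 787 ± 9.06 CPM. Loxl2 and Epas1 fell (log2 fold changes of -2.76 and -1.52), and Hif1a itself was at -0.05 and did not pass. The EVadMu libraries, in which this and the preceding list rose, again had the higher mitochondrial ribosomal RNA share. Their markers of fibroblasts, glia and macrophages were lower (medians -3.75, -2.79 and -2.84).

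Nuclear genes of respiratory complex I were higher, 32 of 38 with 0 lower, also when adjusted over the list alone, at a median of 0.56 (0.37 to 0.67; camera adjusted p = 2.57e-06). The call was lost with the correlation estimated from the data (adjusted p = 0.0855 with an estimated correlation). Ndufs3 rose from 40.8 ± 1.8 to 92.2 ± 0.77 CPM and Ndufv1 from 106 ± 3.8 to 198 ± 12.4 CPM, and Ndufs8 and Ndufa4 rose by 0.99 ± 0.055 and 0.95 ± 0.044 on the log2 scale. The other 6 members did not pass. In these libraries mitochondrial ribosomal RNA was higher (0.565 to 0.604% against 0.0524 to 0.0541% of counts), while fibroblast and glia markers had medians of -3.75 and -2.79.

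Endothelial and mural cell markers were lower, 23 of 25 with 1 higher, also when adjusted over the list alone, at a median of -2.35 (-2.91 to -1.21; camera adjusted p = 4.23e-06). The pericyte proteoglycan gene Cspg4 fell from 299 ± 9.03 to 12.2 ± 0.34 CPM, the receptor gene Pdgfrb from 116 ± 2.83 to 9.68 ± 0.38 CPM, the smooth muscle actin gene Acta2 from 63.1 ± 0.97 to 0.61 ± 0.074 CPM and the endothelial adhesion gene Pecam1 from 79.9 ± 3.8 to 20.1 ± 0.42 CPM. The clotting factor carrier gene Vwf rose by 1.45, and Mmrn2 was at 0.14 and did not pass.

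Glycolysis genes were higher, 18 of 22 with 3 lower, also when adjusted over the list alone, at a median of 1.42 (0.94 to 1.61; camera adjusted p = 6.98e-06). The lactate exporter gene Slc16a3 rose from 7.99 ± 0.17 to 188 ± 3.13 CPM and lactate dehydrogenase Ldha from 270 ± 5.54 to 1153 ± 35.5 CPM, beside Hk2 and Slc2a1. The hypoxia list also holds Ldha, Hk2 and Slc2a1. Pfkm, Slc2a3 and Pfkp fell (log2 fold changes of -0.41, -0.27 and -0.19), and Ldhb was at -0.01 and did not pass. Gapdh had 94 to 375 counts per library, a low level for a gene of this pathway with many pseudogenes, so its log2 fold change of 1.53 ± 0.12 is uncertain. Mitochondrial ribosomal RNA took 0.565 to 0.604% of counts in EVadMu against 0.0524 to 0.0541%, and markers of fibroblasts and glia were lower (medians -3.75 and -2.79).

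Among channels, receptors and peptides of sensory neurons, 36 of 47 were lower and 8 higher, also when adjusted over the list alone, at a median of -1.13 (-1.93 to -0.72; camera adjusted p = 9.35e-06). The receptor gene Ret fell from 578 ± 12.3 to 112 ± 6.41 CPM, the pain-related sodium channel gene Scn9a from 255 ± 9.47 to 30.3 ± 2.69 CPM, the potassium channel gene Kcna2 from 289 ± 5.65 to 36.3 ± 3.94 CPM and the neurturin co-receptor gene Gfra2 from 123 ± 1.37 to 13.9 ± 0.53 CPM. The natriuretic peptide gene Nppb, the calcium-binding protein gene Pvalb and the tyrosine hydroxylase gene Th rose by 3.90, 2.21 and 2.02, Runx3 and Piezo1 by 1.40 and 1.28, and Kcnk2, Asic3 and Slc17a7 by 0.31, 0.29 and 0.14. Kcns3 (-0.14), Runx1 (-0.04) and Slc17a8 (0.06) did not pass. Glia and fibroblast markers were lower alongside, at medians of -2.79 and -3.75.

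Pan-neuronal markers were lower, 26 of 32 with 4 higher, also when adjusted over the list alone, at a median of -0.99 (-1.23 to -0.76; camera adjusted p = 1.12e-05). Tubb3, the neuronal tubulin gene, fell from 1217 ± 14.6 to 512 ± 6.00 CPM, the growth cone gene Gap43 from 237 ± 7.16 to 53.4 ± 3.15 CPM, the microtubule protein gene Mapt from 226 ± 4.86 to 70.9 ± 2.01 CPM and the RNA-binding protein gene Elavl4 from 89.6 ± 5.26 to 14.5 ± 1.67 CPM. Chgb, Snap25, Vamp1 and Thy1 rose by 0.44, 0.29, 0.26 and 0.11, while Nefh (0.06) and Uchl1 (-0.07) did not pass. The markers of non-neuronal cells were lower in the same libraries by larger medians, from -2.35 for endothelial and mural cells to -3.75 for fibroblasts.

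Macrophage and leukocyte markers were lower, 24 of 26 with 1 higher, also when adjusted over the list alone, at a median of -2.84 (-3.60 to -1.95; camera adjusted p = 7.04e-05). The lysozyme gene Lyz2 fell from 65.5 ± 2.15 to 0.88 ± 0.19 CPM, the perforin-like gene Mpeg1 from 17 ± 0.33 to 0.92 ± 0.33 CPM and the actin regulator gene Coro1a from 37.7 ± 0.24 to 7.07 ± 0.67 CPM. The lysosomal membrane gene Cd68 was the exception and rose from 12.9 ± 1.90 to 131 ± 3.23 CPM. Tyrobp was at -0.30 and did not pass.

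All 12 tested mRNAs encoded by the mitochondrial genome were lower, over all genes and adjusted over the list alone, at a median of -1.43 (-2 to -1.26; camera adjusted p = 7.97e-05). This call, too, was lost when the correlation was estimated (adjusted p = 0.141 with an estimated correlation). The cytochrome oxidase subunit mRNA mt-Co1 fell from 5439 ± 178 to 1148 ± 44.2 CPM, mt-Cytb from 1910 ± 73.9 to 823 ± 23.8 CPM, mt-Nd5 from 1519 ± 57.2 to 567 ± 10.4 CPM and mt-Nd1 from 1345 ± 12.9 to 548 ± 12.5 CPM. Together these mRNAs took 1.26 to 1.34% of the EVMu counts and 0.393 to 0.405% of the EVadMu counts. The mitochondrial ribosomal RNAs went the other way, mt-Rnr1 from 124 ± 2.02 to 2306 ± 137 CPM and mt-Rnr2 from 388 ± 9.80 to 3717 ± 139 CPM. mt-Co2, mt-Co3 and mt-Atp6 had far fewer counts than mt-Co1 in every library, and their reads can be shared with nuclear copies of mitochondrial DNA.

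**Figure D3:**
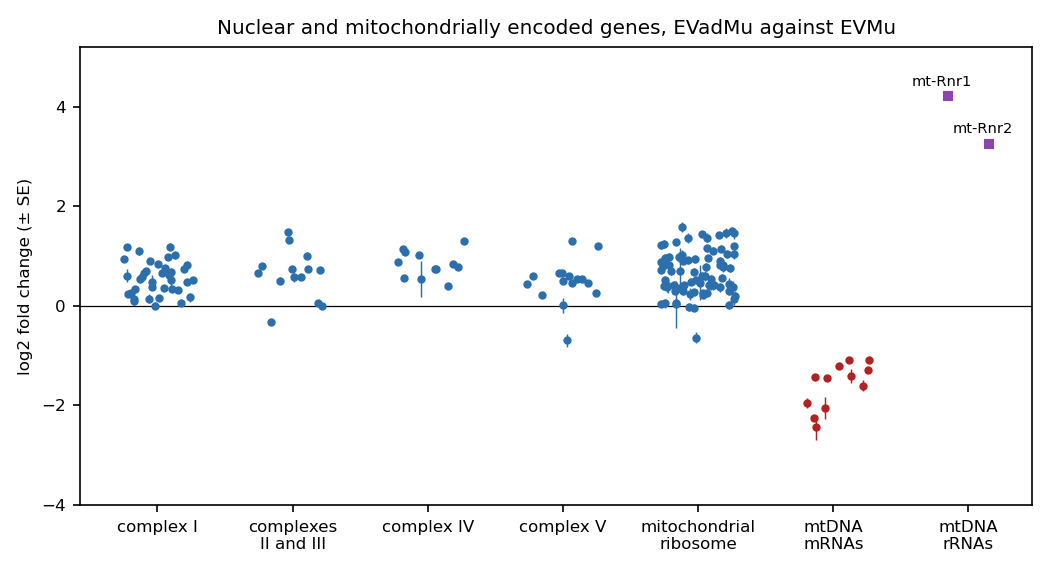
Log2 fold change of EVadMu against EVMu (± SE) for nuclear genes of the respiratory complexes and the mitochondrial ribosome (blue), mRNAs encoded by mitochondrial DNA (red) and the mitochondrial rRNAs (purple squares). Nuclear complex I genes had a median of 0.56 and mitochondrially encoded mRNAs one of -1.43, while mt-Rnr1 and mt-Rnr2 stood at 4.21 and 3.26.

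Nuclear genes of complex IV were higher, 11 of 12 with 0 lower, also when adjusted over the list alone, at a median of 0.81 (0.65 to 1.05; camera adjusted p = 0.000236). Cox6a1 rose from 173 ± 9.47 to 426 ± 12.5 CPM and Cox4i1 from 229 ± 6.40 to 392 ± 21.7 CPM, and Cox7a2l and Cox7a2 rose by 1.15 ± 0.045 and 1.08 ± 0.056 on the log2 scale. Cox7a1, an isoform of heart and skeletal muscle, was at 0.55 and did not pass. The mitochondrially encoded subunit mRNA mt-Co1 had a log2 fold change of -2.24 in the same libraries, where the mitochondrial ribosomal RNA share was 0.565 to 0.604% against 0.0524 to 0.0541% and fibroblast and glia markers were lower (medians -3.75 and -2.79).

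Genes of mitochondrial biogenesis and mitochondrial DNA maintenance were higher, 17 of 23 with 1 lower, also when adjusted over the list alone, at a median of 0.69 (0.44 to 0.84; camera adjusted p = 0.000237). Ppargc1a, the coactivator PGC-1α, rose from 11.7 ± 1.72 to 77.6 ± 1.8 CPM, the deacetylase gene Sirt1 from 24.2 ± 1.73 to 130 ± 3.15 CPM, the mitochondrial protease gene Lonp1 from 117 ± 4.87 to 422 ± 9.63 CPM and the related coactivator gene Pprc1 from 63.4 ± 1.68 to 168 ± 3.64 CPM. The AMP-activated kinase gene Prkaa1 fell by 0.50, and Esrra (0.01), Polg (0.04), Tfb1m (0.10), Prkaa2 (0.13) and Sirt3 (0.19) did not pass. Also different between the groups were the mitochondrial ribosomal RNA share (0.565 to 0.604% against 0.0524 to 0.0541%), the mitochondrially encoded mRNAs (median -1.43) and the markers of fibroblasts and glia (medians -3.75 and -2.79).

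Complex V genes were higher, 14 of 16 with 1 lower, also when adjusted over the list alone, at a median of 0.52 (0.45 to 0.61; camera adjusted p = 0.000831, and adjusted p = 0.166 with an estimated correlation). Atp5g1 rose from 79.6 ± 2.48 to 197 ± 5.77 CPM and the catalytic subunit gene Atp5b from 816 ± 8.11 to 1119 ± 5.64 CPM, with Atp5l and Atp5d up by 1.2 and 0.66 on the log2 scale. Dmac2l fell by 0.69 and Atp5k was at 0.01 and did not pass. Complex II and III genes were higher, 11 of 14 with 1 lower, also when adjusted over the list alone, at a median of 0.70 (0.51 to 0.81; camera adjusted p = 0.0031, and adjusted p = 0.125 with an estimated correlation). Cycs, the gene of cytochrome c, rose from 72.6 ± 4.80 to 203 ± 7.13 CPM and Uqcrq from 56.1 ± 2.77 to 141 ± 7.52 CPM, and Uqcrc2 and Cyc1 rose by 0.81 and 0.73. Uqcrc1 fell by 0.33, and Sdha (-0.01) and Sdhc (0.07) did not pass. The mitochondrially encoded mRNAs mt-Atp6 of complex V and mt-Cytb of complex III were lower (log2 fold changes of -1.60 and -1.22) and mitochondrial ribosomal RNA was higher in these libraries, as given above.

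Synaptic vesicle and release genes were lower, 21 of 28 with 5 higher, also when adjusted over the list alone, at a median of -0.61 (-1.02 to -0.21; camera adjusted p = 0.00324). The vesicle protein gene Sv2c fell from 482 ± 5.44 to 208 ± 8.06 CPM, the active zone genes Bsn and Pclo from 139 ± 7.05 to 35.6 ± 2.41 CPM and from 64.7 ± 3.30 to 13.6 ± 0.92 CPM, and the calcium sensor gene Syt7 from 117 ± 4.63 to 35.8 ± 1.63 CPM. Stx1a, Cplx1, Vamp2, Snap25 and Syp rose by 0.86, 0.57, 0.33, 0.29 and 0.15, while Rab3a (-0.08) and Syt4 (0.06) did not pass. Glia markers were lower alongside (median -2.79).

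TCA cycle and pyruvate entry genes were higher in 20 of 27 and lower in 4, also when adjusted over the list alone, at a median of 0.35 (0.16 to 0.63; camera adjusted p = 0.00338, and adjusted p = 0.198 with an estimated correlation). The pyruvate dehydrogenase subunit gene Pdhb rose from 106 ± 2.57 to 443 ± 8.13 CPM, and Pdk1, whose kinase switches that enzyme off, rose from 17.6 ± 0.26 to 68.3 ± 0.53 CPM. The malate dehydrogenase gene Mdh2 rose by 0.98 ± 0.033 on the log2 scale. Pdk2, Fh1, Idh2 and Ogdh fell (-0.92, -0.44, -0.34 and -0.32), and Sucla2 (-0.08), Sdha (-0.01) and Cs (0.04) did not pass. Mitochondrial ribosomal RNA was higher and mitochondrially encoded mRNAs were lower in the same EVadMu libraries.

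Immediate early genes were higher in 22 of 31 and lower in 7, also when adjusted over the list alone, at a median of 0.94 (0.26 to 1.30; camera adjusted p = 0.005, and adjusted p = 0.155 with an estimated correlation). The MAP kinase phosphatase gene Dusp4 rose from 20.7 ± 1.06 to 202 ± 6.66 CPM and the AP-1 subunit gene Junb from 41.1 ± 2.30 to 232 ± 9.71 CPM, with Klf4 and Ier3 up by 2.28 ± 0.060 and 2.14 ± 0.052 on the log2 scale. Egr2, Egr3 and Nr4a1 fell, with log2 fold changes of -2.54, -2.38 and -2.07, as did Dusp6, Fos, Arc and Nr4a2 (-0.94, -0.84, -0.77 and -0.52), while Klf2 (-0.19) and Ccn2 (0.07) did not pass. The same libraries held more mitochondrial ribosomal RNA (0.565 to 0.604% of counts against 0.0524 to 0.0541%) and lower levels of fibroblast and glia markers (medians -3.75 and -2.79).

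The remaining 9 lists did not pass the camera test, though members moved in both directions. Skeletal muscle transcripts came nearest (adjusted p = 0.0504), with 16 of 29 higher and 4 lower, also when adjusted over the list alone: skeletal actin Acta1 rose from 1.41 ± 0.19 to 14.3 ± 1.3 CPM and the calcium pump gene Atp2a1 from 0.85 ± 0.30 to 5.90 ± 0.88 CPM, while Tpm2 fell from 15.3 ± 1.14 to 3.49 ± 0.25 CPM and the synapse kinase gene Musk from 5.04 ± 0.91 to 0.21 ± 0.18 CPM. The list passed when 1 library was left out, for 5 of the 6 libraries (adjusted p from 0.00896 to 0.0417), and did not without EVadMu replicate 1 (0.0657). Cholesterol synthesis genes (adjusted p = 0.056) were lower in 18 of 25 and higher in 6, also when adjusted over the list alone. Hmgcs1 fell, with a log2 fold change of -1.24 ± 0.036, and Insig1 and Fdft1 rose by 1.10 ± 0.035 and 0.95 ± 0.037. This list passed without EVMu replicate 1 (0.046) or EVMu replicate 3 (0.047).

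Regeneration-associated genes, which injured sensory neurons switch on as axons regrow, were lower in 28 of 49 and higher in 17 (29 and 17 when adjusted over the list alone), at a median of -0.53 (-1.01 to 0.05; adjusted p = 0.0622). L1cam and the calcium channel subunit gene Cacna2d1 fell, with log2 fold changes of -2.71 and -3.06, and the stress-induced genes Ddit3 and Gadd45a rose by 3.55 and 2.23. Mitochondrial dynamics, transport and mitophagy genes were higher in 16 of 32 and lower in 9 (adjusted p = 0.197), the same adjusted over the list alone. The mitophagy receptor genes Bnip3 and Bnip3l rose by 3.21 ± 0.057 and 1.90 ± 0.038, the autophagy adaptor gene Sqstm1 from 897 ± 12.7 to 3759 ± 8.85 CPM, and the axonal motor gene Kif5a fell by 1.60 ± 0.032.

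Of p53 and apoptosis genes, 17 of 34 were higher and 13 lower (adjusted p = 0.286), with Cdkn1a, Mdm2, Bax and Gadd45a up by 1.34, 1.88, 1.47 and 2.23 on the log2 scale. Fatty acid oxidation genes were lower in 14 of 26 and higher in 8 (15 and 8 when adjusted over the list alone; adjusted p = 0.286): Acat1 and Cpt1a fell (-1.67 and -1.11 on the log2 scale), and Acot2 rose by 2.14. Of cAMP, PI3K-AKT and growth factor genes, 22 of 40 were lower and 14 higher (adjusted p = 0.308), with Pik3r1 and Fgf2 down by log2 fold changes of -2.42 and -3.41 and Tsc1 up by 1.42. Vesicle biogenesis and uptake genes were higher in 15 of 27 and lower in 11 (adjusted p = 0.527), and the list's median (0.26) and mean (-0.05) differed in sign. In that list Lgals3, Cd63 and Chmp4b rose by 3.24, 1.39 and 1.32, and Itgav fell by 1.92. Inflammatory and NF-kB target genes were higher in 15 of 35 and lower in 12 (adjusted p = 0.538), with Nfkbia and Lcn2 up by 2.06 and 2.67 and Vcam1 and Ccl2 at -1.93 and -1.71. The counts of the p53, growth factor, vesicle and NF-kB lists were the same adjusted over the list alone.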

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

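Library sizes without scaling factors were the setting chosen only after the results were seen. Over 14 other settings the number of called genes lay between 12693 (stricter filter) and 14771 (no filter), against 13597, and leaving out single libraries gave 13379 to 13622. DESeq2 called 13314 genes, of which 12456 were among the 13597, with the same sign. The named genes that the rule picked kept their direction and their side of the threshold in all 2030 comparisons with another setting. Members named only for going against their list or for not passing were not among them. Every setting drew on the same libraries from which the rule picked genes by small p or large fold. Such genes were likely to stay past the threshold, so their stability says little about other genes. Some list members did change sides. With upper-quartile factors 2 stress-response genes were called lower, against 1, and with library sizes only 7 TCA cycle genes, against 4. Replicate numbers did not pair the libraries (same-number correlations of deviations -0.007, -0.004 and -0.01), and with the replicate block 13409 genes were called and skeletal muscle transcripts passed (adjusted p = 0.0334), with no other list changing its call. With an estimated correlation 6 called lists missed the threshold: complex I (0.0855), mitochondrially encoded mRNAs (0.141), complex V (0.166), complex II and III (0.125), TCA cycle (0.198) and immediate early genes (0.155). Fry, which tests whether a list's own genes move on balance and does not compare it with other genes, passed the 9 lists that camera did not: skeletal muscle (0.000177), cholesterol (1e-05), regeneration-associated (1.66e-06), mitochondrial dynamics (8.95e-06), p53 (8.7e-06), fatty acid oxidation (0.000913), growth factor signalling (0.000145), vesicle biogenesis (0.000765) and NF-kB (0.000254). Leaving out single libraries gave skeletal muscle 0.00896, 0.0155 and 0.0154 without EVMu replicates 1, 2 and 3, 0.0417 and 0.0181 without EVadMu replicates 2 and 3, and 0.0657 without EVadMu replicate 1. It gave cholesterol synthesis 0.046 to 0.0777, past the threshold without EVMu replicate 1 (0.046) or 3 (0.047). With library sizes only, skeletal muscle (0.0311) and cholesterol synthesis (0.0489) passed, the NF-kB list median turned from 0.10 to -0.018, the cytosolic ribosome median went from 1.46 to 1.35, and the median of all tested genes was -0.133 against -0.02. DESeq2, which tested 25374 genes, put that median at 0.139. The cause of these changes was not tested, apart from fry's and the block's own construction. Depth limits genes under a few counts per library, for which folds are bounds or ratios.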

Other observations

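The 7 gene lists below, and the tests on markers, scaling and total mitochondrial RNA, were chosen only after the results were seen. Translation factors were higher, as were ribosome genes: 34 of 35 initiation and elongation factor genes rose and 0 fell, at a median log2 fold change of 1.29 (95% bootstrap interval 1.18 to 1.44; limma camera adjusted p = 7.76e-11, and adjusted p = 0.0408 with an estimated correlation). Eif1, which helps select the start codon, rose by 2.06, the helicase gene Eif4a1 by 1.88 and Eif4ebp1, whose protein restrains cap-dependent initiation, by 2.45. Of 20 cytosolic tRNA synthetase genes, 19 rose and 0 fell (median 0.94, adjusted p = 3.2e-07, and adjusted p = 0.0435 with an estimated correlation), with Rars, Tars and Sars up by 1.97, 1.88 and 1.79. Heat shock chaperone genes were higher in 20 of 28 and lower in 5 (median 0.72, adjusted p = 0.000344, and adjusted p = 0.0672 with an estimated correlation). Hspa1a rose from 8.22 ± 1.79 to 327 ± 9.15 CPM (SD, n = 3 per group) and its near-identical copy Hspa1b from 11.7 ± 0.60 to 412 ± 9.58 CPM, so reads may be split between them in either group, and the chaperone genes Hspa9 and Hspe1 of the mitochondrial matrix rose by 2.22 and 1.88. Markers of fibroblasts and glia were lower in the libraries in which these lists rose (medians -3.75 and -2.79).

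Of 37 proteasome genes, 32 rose and 4 fell (median 0.52, limma camera adjusted p = 1.5e-05, and adjusted p = 0.0804 with an estimated correlation). The immunoproteasome genes Psmb9, Psmb8 and Psmb10, which interferon induces, fell, with log2 fold changes of -4.84, -2.84 and -1.26, while Psmd8 rose by 1.61. Lysosomal genes were higher in 35 of 46 and lower in 10 (median 0.80, adjusted p = 4.82e-05, and adjusted p = 0.0569 with an estimated correlation): the galactosidase gene Gla rose by 2.47 and the sialidase gene Neu1 by 1.99, and Manba and Lipa fell (-1.86 and -1.67). Basement membrane genes were lower in 22 of 26 and higher in 2 (median -2.85, adjusted p = 2.15e-07, and adjusted p = 0.0768 with an estimated correlation), with Col15a1, Nid2 and Hspg2 down by log2 fold changes of -6.05, -5.72 and -4.10 and Lama1 up by 0.45. Actin and myosin genes were lower in 23 of 28 and higher in 3 (median -0.76, adjusted p = 5.31e-05, and adjusted p = 0.0408 with an estimated correlation): Actb fell by 1.22, and Myl9, expressed in smooth muscle, fell by 4.64. Beside all 4 lists of this paragraph, markers of fibroblasts, glia and macrophages were lower (medians -3.75, -2.79 and -2.84) and mitochondrial ribosomal RNA took 0.565 to 0.604% of counts against 0.0524 to 0.0541%.

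The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 13597 called genes and 6991 of at least 2-fold, and the highest of the other splits gave 0 of either in edgeR's test, with at most 63 genes at an unadjusted p under 0.05, so 1 split of 10 reached each real count. For the lists, 5 of the 10 splits called as many as the real one (24), and the highest other called 25. The other splits mix both groups on each side and so still hold part of their contrast, while the rest adds to the spread within a side. They therefore cannot decide whether chance gave the real calls.

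Markers of non-neuronal cells fell in EVadMu. Fewer such cells beside unchanged neurons would raise the share of neuronal transcripts, but pan-neuronal markers had a median log2 fold change of -0.99 (-1.23 to -0.76), and a scaling error would move both sets alike, while fibroblast and neuronal medians differed by -2.76 (-4 to -1). Both values argue against these explanations as the whole cause. A loss of glia with unchanged expression stays open: the 25th and 75th percentiles of the 30 glia markers lay 2.61 apart, but a marker that other cells also express would fall less. A smaller number of non-neuronal cells together with altered expression in the cells that remained may account for the fall and was not tested. The kind of vesicle is the difference that the design names. A difference in culture preparation or batch between the groups, if there was one, could not be told from it. Without a group given no vesicles, more such cells in EVMu cannot be told from fewer in EVadMu.

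Mitochondrial ribosomal RNA rose while mitochondrially encoded mRNAs fell. A lower amount of all mitochondrial RNA would lower both, but the smaller rise, of mt-Rnr2, was 3.26 (3.20 to 3.32). That rise is part of the pattern in question, and poly(A)-selected libraries may not measure the amount of rRNA. A lower amount of mitochondrial RNA is therefore not excluded. Scaling would move nuclear and mitochondrial mRNAs alike, but their medians differed by -1.99 (mitochondrially encoded mRNAs minus complex I, -2.59 to -1.77). A candidate explanation for the rRNA part is that more RNA without a poly(A) tail was carried into the EVadMu libraries: the 10 tested rows of small RNAs without such tails had a median log2 fold change of 1.78 (0.85 to 2.64), 7 passing as higher and 1 as lower, in a test written down before its result was seen. These rows have low counts and several are copies of 7SK that can share reads, and the explanation leaves the fall of the mRNAs open.

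In EVadMu, 205 genes with a mean under 0.1 CPM in EVMu reached at least 0.5 CPM, and 240 did so in the other direction. After thinning to 14853115 counts each, the lowest number of detected genes in an EVadMu library exceeded the highest in an EVMu library by 551. This argues against depth as the cause of the higher number of detected genes in EVadMu. The number covers every gene with a read, so it does not test the 205 genes alone. Reads running on from a neighbouring gene may add to the switched-on genes: the higher neighbour's level, in the rat gene order, was 1.57 higher on the log2 scale for 66 such genes than for 2085 silent ones, and 0.23 higher for the genes that went the other way. The difference lay in the direction written down beforehand and above the central 95% of 10000 permuted differences (-2.05 to 1.42), but that range is lopsided and the two-sided permutation p was 0.0792 (0.0143 one-sided, chosen after the result was seen), so the explanation stays open.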
